A study of Homo sapiens with 45 samples.

How the data were processed

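Polyadenylated RNA of 45 cell line libraries was sequenced as paired reads of 150 bases. Per the labels, reads were aligned to the human genome build GRCh38 with STAR 2.6.0a, and limma was named for the submitters' own comparisons. The counting tool, the gene annotation and the strand setting were not given in the sources used here. The deposited table held raw counts per gene symbol, 57353 symbols by 45 libraries, and every column was matched to a sample. Its values were checked to be whole numbers with no negative entries. All libraries were in the same unit, and no normalisation by the authors had been applied to them.

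Of the symbols, 16974 had no count in any library, 2 were repeated and were kept apart, and 27 had been turned into dates by spreadsheet software, which held 0.19% of all counts. Gene types, positions and identifiers came from GENCODE release 29, in which 56598 symbols were found. Library totals ranged from 21.0 to 36.7 M counts. Reads carried no molecular identifiers, so counts include any amplification copies, and no interval for counting error was set around single libraries.

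Groups were taken from the labels, 5 in each of 3 lines with 3 libraries each. Within each line, 4 comparisons were made: siNT_E2 against siNT, and siER_E2, siFOXA1_E2 and siMDC1_E2 each against siNT_E2. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group, totals were scaled by TMM, and the 15 libraries of a line were fitted together with the quasi-likelihood method (glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p below 0.05. Differences between lines in each of the 4 effects (MM134 minus HCC1428 and MM330 minus HCC1428) were tested as interaction contrasts in a fit of all 45 libraries. Levels are CPM as edgeR computes them from TMM-scaled totals within a line, as mean and SD. Fold changes are given on the log2 scale with the SE of the quasi-likelihood fit. In all, 12 comparisons within lines and 8 differences between lines were tested.

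Reversal of the E2 response by a knockdown was counted as genes called in both comparisons with opposite signs, and overlap of a pair of knockdowns as genes called in both with the same sign. The number expected with independent calls was the product of both numbers of called genes divided by the genes tested. Because compared contrasts shared the siNT_E2 libraries, correlations across genes and covariances were also computed in 100 simulated sets per pair of comparisons. In these sets, group means were equal and deviations between replicates were resampled. Numbers of reversed and shared genes were also counted in 20 fits per line of negative binomial counts with equal group means. The shared control group of 3 libraries could not be divided into parts with at least 2 libraries each.

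The 19 gene lists held 459 genes and were written from general knowledge before the data were examined. They were E2-induced targets, E2-repressed targets, Mitosis, DNA replication, DNA damage response, p53 targets, Luminal epithelium, Basal and mesenchymal, Epithelial adhesion, Interferon response, Unfolded protein and amino acid stress, Cholesterol synthesis, Ribosome biogenesis, Heat shock, Hypoxia and glycolysis, Mitochondrially encoded, Fibroblast, Immune cell and Endothelial. ESR1, FOXA1 and MDC1 were left out of every list. Lists with at least 5 measured members were tested by camera on voom weights in limma 3.58.1, with a preset correlation of 0.01 between genes, against all other genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way without reference to other genes, were run as alternatives.

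The genes to be named were set by a rule in the same way. It took ESR1, FOXA1 and MDC1 in every group, the 3 highest and 3 lowest called protein-coding genes of a comparison with at least 10 CPM in either group and no overlap between groups, up to 3 members of each called list by smallest p, a panel of estrogen-responsive genes (TFF1, GREB1, PGR, PDZK1, MYC and CXCL12), the 3 highest and 3 lowest genes of each difference between lines, and the levels of CDH1, CTNNA1, ERBB2 and WNT4 in siNT. Fewer were printed where genes had few counts in a group, and the highest and lowest genes of the line differences were left out for that reason. Members named because they moved against their list, and other genes marked as such, were chosen after their values were seen.

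Alternatives planned beforehand were RLE scaling, no filter on low counts, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, a fit of the compared libraries only, camera with an estimated correlation, and fry. A term for a class of libraries with more counts at processed pseudogenes (a share above 0.248%), and a fit of the other libraries alone, were added after the data were seen. The pipeline was tested on simulated data with 200 changed genes. Counts were drawn from the line means and the spread of each gene over all libraries of a fit. The changes, and a shift of the DNA replication list, were placed in the siMDC1_E2 group. The pipeline recovered 82.7%, 86.2% and 100% of changes of 1.5-fold, 2-fold and 4-fold in MM134, with 4.8% false calls. In MM330 the corresponding shares were 68.3%, 80.6% and 98.5% with 5.6% false calls, and in HCC1428 they were 69.6%, 86.2% and 100% with 3.8%. For the difference between MM134 and HCC1428 the shares were 65.8%, 76.2% and 93.4%, with 6.2% false calls. Genes varied independently in these data and few were changed, so false calls in the real fits may differ. Whether equal replicate numbers marked paired libraries was checked by correlating replicate deviations. The correlation was above 0.1 in every pair only for E2 in HCC1428 (0.15 and 0.24), and single pairs of all comparisons ranged from -0.43 to 0.43, so numbers were not used to pair the groups. They were kept as a block among the alternatives, where MDC1 knockdown in HCC1428 called 4238 genes instead of 5319.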

Results

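Messenger RNA was sequenced from 3 breast cancer cell lines to compare how estrogen changes gene expression in lobular and ductal carcinoma cells, and how far that change depends on the estrogen receptor, FOXA1 and MDC1. MM134 (MDA-MB-134-VI) and MM330 (MDA-MB-330) derive from invasive lobular carcinoma, a breast cancer whose cells typically lose cell-to-cell adhesion, and HCC1428 derives from invasive ductal carcinoma. Each line had 5 groups of 3 libraries after 3 days without hormone. The siNT group received a non-targeting small interfering RNA (siRNA, a short duplex that directs degradation of a matching transcript) and the vehicle, 0.01% ethanol. The siNT_E2 group received the same siRNA and 100 pM estradiol (E2), the natural ligand of the estrogen receptor, for 24 h. The siER_E2, siFOXA1_E2 and siMDC1_E2 groups received E2 and an siRNA against the receptor gene ESR1, against FOXA1, or against MDC1. Totals were 24.8 to 36.7 M counts per library in MM134, 21.0 to 36.6 M in MM330 and 23.2 to 35.1 M in HCC1428. The labels did not say whether libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries. Every knockdown group received E2 and was compared with the siNT_E2 libraries of its line, which also formed an arm of the E2 comparison.

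Libraries differed in the share of counts at processed pseudogenes, which are intronless copies of expressed genes. It was 0.337% to 0.494% in 11 libraries and 0.123% to 0.158% in the other 34, and the boundary did not follow the groups. The 11 libraries with the higher share were 2 of MM134, 4 of MM330 and 5 of HCC1428. For the HCC1428 siNT and siER_E2 groups, only 1 library each had the lower share. Counts of called genes are therefore also given for the libraries with the lower share alone. Mitochondrially encoded transcripts took 12.6% ± 1.5 (SD, n = 3) of the counts in HCC1428 siNT_E2 and 15.4% to 17.3% in the other HCC1428 groups. Their group means were 8.77% to 9.81% in MM134 and 11.4% to 12.5% in MM330.

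**Figure D1:**
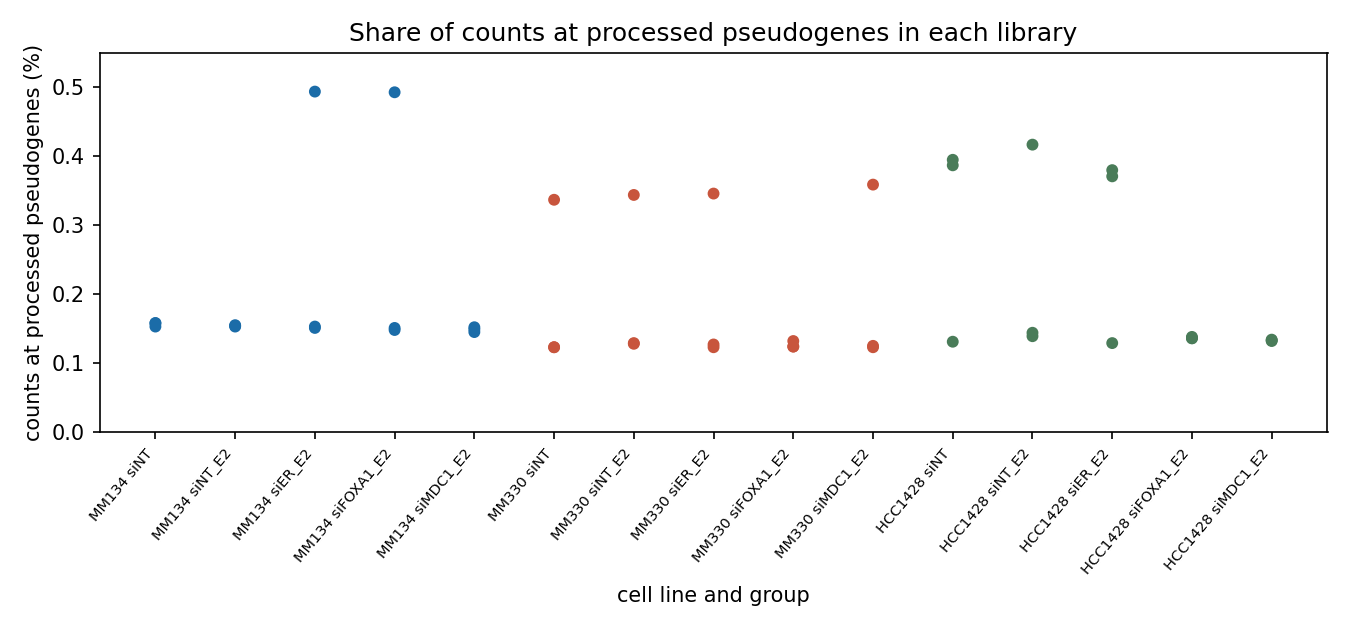
Share of counts at processed pseudogenes (percent, vertical axis) in each of the 45 libraries, by cell line and group, with 1 point per library. The 11 higher libraries lie between 0.337% and 0.494% and the other 34 between 0.123% and 0.158%.

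The depth of each knockdown was read from the targeted transcripts in every group. ESR1 (ENSG00000091831.23, GRCh38 chromosome 6, 151656691 to 152129619) encodes estrogen receptor alpha. In MM134 it stood at 344 ± 21 CPM in siNT, 573 ± 7.4 in siNT_E2, 65.9 ± 3.3 in siER_E2, 117 ± 3.9 in siFOXA1_E2 and 129 ± 0.39 in siMDC1_E2 (mean ± SD, n = 3). The MM330 levels in the same order were 289 ± 4.7, 275 ± 9.2, 21.5 ± 3.8, 201 ± 4.4 and 142 ± 1.1 CPM, and those of HCC1428 were 555 ± 9.8, 413 ± 7.4, 206 ± 7.4, 371 ± 0.69 and 380 ± 13 CPM. FOXA1 (ENSG00000129514.5, chromosome 14, 37589984 to 37596059) encodes a factor that opens chromatin for the receptor. It fell from 471 ± 12 to 120 ± 0.53 CPM with its own siRNA in MM134, from 486 ± 13 to 134 ± 18 in MM330 and from 271 ± 8.5 to 86.6 ± 4.7 in HCC1428. MDC1 (ENSG00000137337.14, chromosome 6, 30699807 to 30717889) encodes a scaffold protein that gathers repair factors at DNA breaks. With its own siRNA it fell from 186 ± 2.9 to 42.7 ± 3.7 CPM in MM134, from 195 ± 7.2 to 39.8 ± 3.9 in MM330 and from 168 ± 11 to 43.9 ± 3.3 in HCC1428. Every library of a knockdown group lay below every siNT_E2 library of its line for the targeted gene.

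**Figure D2:**
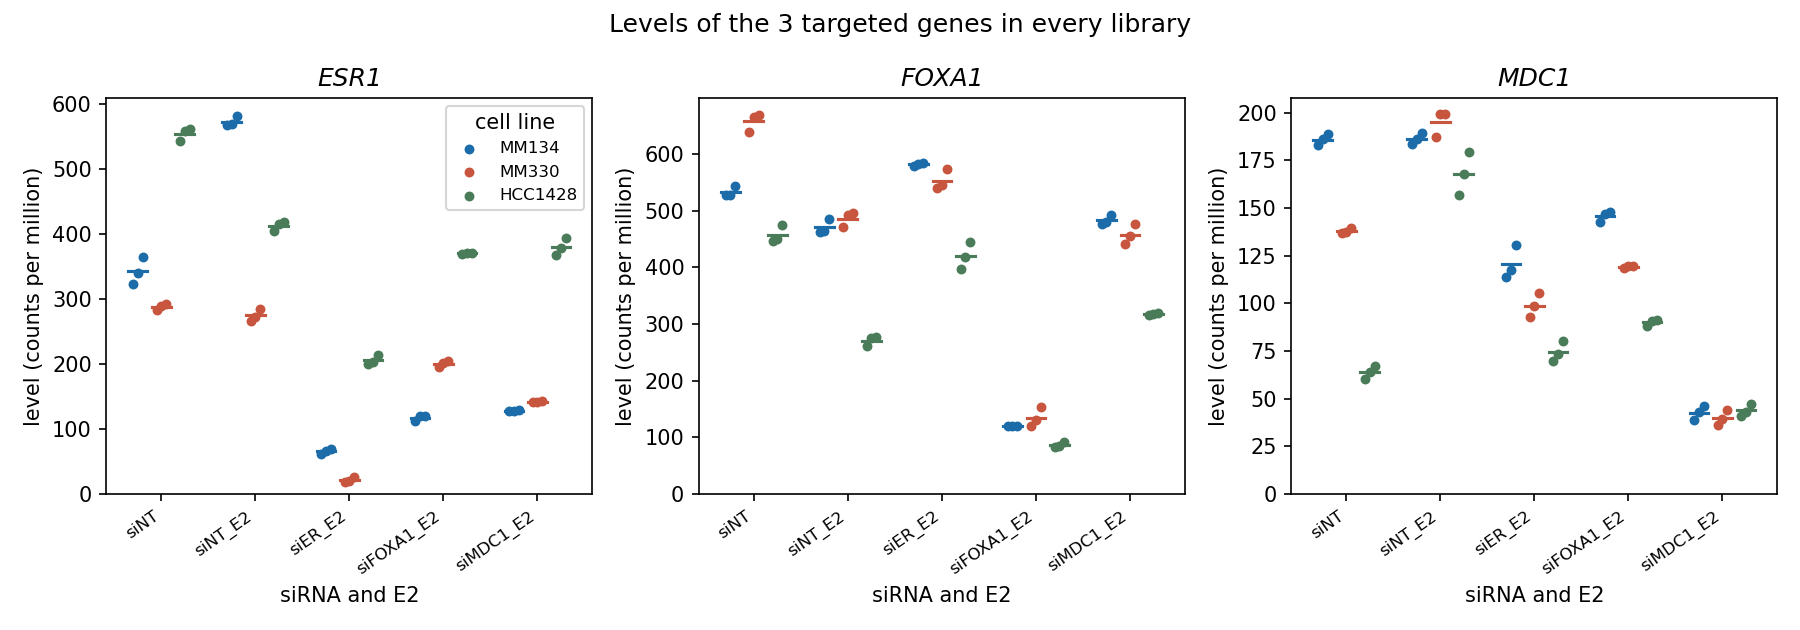
Levels (CPM, vertical axis) of ESR1, FOXA1 and MDC1 by siRNA and E2 group in the 3 lines, with 1 point per library and a bar at the mean of 3 libraries. MDC1 in siMDC1_E2 averaged 42.7 CPM in MM134, 39.8 in MM330 and 43.9 in HCC1428.

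Genes that mark the lines were read in siNT. CDH1, which encodes E-cadherin, stood at 23.8 ± 2 CPM in MM134, 729 ± 5.5 in MM330 and 1200 ± 25 in HCC1428. CTNNA1, which encodes its partner alpha-catenin, stood at 559 ± 19, 41.2 ± 1.9 and 289 ± 4.2 CPM in the same order. The growth factor receptor gene ERBB2 reached 15300 ± 110 CPM in MM330, against 207 ± 8.3 in MM134 and 482 ± 6.3 in HCC1428. WNT4, a secreted signalling ligand, stood at 7.64 ± 1, 0.512 ± 0.12 and 21.3 ± 2.5 CPM.

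The E2 response of each line was measured by comparing siNT_E2 with siNT. In MM134, 9648 of 17744 genes were called, 4825 higher and 4823 lower with E2, of which 539 rose and 1054 fell by 2-fold or more; 10029 were called in the libraries with the lower pseudogene share. ESR1 itself rose (log2 0.74 ± 0.04 SE, adjusted p = 3.6e-13), FOXA1 fell (-0.18 ± 0.03, adjusted p = 5.7e-06) and MDC1 stayed at 186 CPM (adjusted p = 0.96). The classical estrogen target TFF1 (ENSG00000160182.2, chromosome 21, 42362282 to 42366594), which encodes a mucosal peptide, rose 24.8-fold (log2 4.63 ± 0.09). GREB1 (ENSG00000196208.13, chromosome 2, 11482341 to 11642788), which encodes a cofactor of the receptor, rose 12.7-fold to 570 CPM. PDZK1 rose 43.1-fold and the growth regulator MYC 6.45-fold, while the chemokine gene CXCL12 rose 3.92-fold. The largest rises among genes at 10 CPM or more were those of the surface marker CD34 (log2 6.49 ± 0.29), PGLYRP2 (5.75 ± 0.08) and ASIC2 (5.54 ± 0.15). The largest falls were those of DEPP1 (-5.24 ± 0.15), a regulator of autophagy, FBN2 (-3.03 ± 0.07) and NXPH1 (-3.03 ± 0.12). All 49 measured E2-induced targets rose (median log2 1.66) and 11 of 12 E2-repressed targets fell (median -1.38), with PDCD4 rising. All 38 DNA replication genes rose, by a median of 0.51, whereas Mitosis genes had a median of 0.13 and that call was lost with an estimated correlation (adjusted p = 0.34). Ribosome biogenesis (median 0.79, 27 of 28 members, 28 adjusted over the list alone), Heat shock (0.64, all 14) and Cholesterol synthesis (0.44, 17 of 22) also rose. HSPB1, which encodes a small heat shock protein, more than doubled from 758 to 1680 CPM.

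In MM330, 4690 of 17834 genes were called with E2, 2437 higher and 2253 lower, and 3092 in the libraries with the lower pseudogene share. ESR1 did not change (log2 -0.07 ± 0.07, adjusted p = 0.52), FOXA1 fell (-0.44 ± 0.06, adjusted p = 4.7e-05) and MDC1 rose (0.50 ± 0.06, adjusted p = 3.1e-06). TFF1 rose 21.6-fold to 4090 CPM and GREB1 4.63-fold to 1550 CPM. MYC rose from 0.456 to 20.3 CPM (log2 5.46 ± 0.19), and the progesterone receptor gene PGR from 0.274 to 4.17 CPM. The vitamin B12 carrier TCN1 rose from 0.0579 to 27.7 CPM. CXCL12 had no count in siNT and 1.18 CPM in siNT_E2, so no fold is given. The largest falls were those of ATP13A5 (-2.66 ± 0.21), the oxygen sensor EGLN3 (-2.40 ± 0.08) and PIP (-2.24 ± 0.18). ERBB2, an E2-repressed target, fell from 15300 to 7530 CPM. Of 48 E2-induced targets 44 rose (median 1.52) and CA12 fell, and 10 of 15 E2-repressed targets fell (median -0.92). DNA replication (0.90, 37 of 38 members) and Mitosis (0.49, 21 of 30, 26 adjusted over the list alone) rose in camera with the preset correlation, but not with an estimated one (adjusted p = 0.12 and 0.22). The same held for falls in Interferon response (-0.36; adjusted p = 0.51), Hypoxia and glycolysis (-0.31; 0.45), Luminal epithelium (-0.15; 0.15) and Epithelial adhesion (-0.12; 0.12). Without siNT replicate 1 the interferon median was -0.30 (adjusted p = 0.051). The luminal call was lost without siNT replicate 1 (adjusted p = 0.053), siNT replicate 3 (0.075) or siNT_E2 replicate 1 (0.08), and TFF3, AGR3 and TFAP2C rose against it.

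In HCC1428, 10028 of 18286 genes were called with E2, 5328 higher and 4700 lower, with 1354 raised and 906 lowered by 2-fold or more; 8869 were called in the libraries with the lower pseudogene share. ESR1 fell (log2 -0.42 ± 0.03, adjusted p = 2.1e-09), FOXA1 fell (-0.75 ± 0.04, adjusted p = 2.5e-11) and MDC1 rose 2.62-fold (1.39 ± 0.06, adjusted p = 3.4e-13). TFF1 rose 19.2-fold, GREB1 6.02-fold, PDZK1 23.1-fold and PGR 1.67-fold, whereas MYC did not change (0.02 ± 0.05, adjusted p = 0.78). EGR3, an early growth response factor, rose most (4.64 ± 0.14), and DEPP1 (-4.42 ± 0.10), WNT11 (-3.16 ± 0.11) and FOXI1 (-2.97 ± 0.20) fell most. Of 49 E2-induced targets 44 rose (45 adjusted over the list alone; median 1.10) and STC2 fell; of 15 E2-repressed targets 10 fell (median -1.11), while CYP24A1 and SMAD6 rose. All 30 Mitosis genes and all 38 DNA replication genes rose, by medians of 2.62 and 2.42. RRM2, which makes nucleotides for DNA synthesis, rose 10.9-fold, and FOXM1, which drives mitotic genes, rose 6.87-fold. DNA damage response genes rose by a median of 0.59 (25 of 33 members), with EXO1 up 9.99-fold. Mitochondrially encoded genes fell (median -0.39; adjusted p = 0.47 with an estimated correlation), by -0.68 in the libraries with the lower pseudogene share.

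Whether E2 acted differently between lines was tested on the difference of log2 fold changes. The MDC1 response was lower than that of HCC1428 by -1.36 in MM134 and -0.90 in MM330 (adjusted p = 3.4e-16 and 8e-11). The ESR1 response was higher by 1.19 and 0.35, and that of FOXA1 by 0.60 and 0.31. MYC differed by 2.69 in MM134 and 5.44 in MM330, and GREB1 by 1.11 and -0.39. TFF1 differed by 0.39 in MM134 (adjusted p = 0.19), a difference called without HCC1428 siNT replicate 3 (0.53, adjusted p = 0.047) and without a filter on low counts (0.36, 0.017; 0.069 to 0.9 in other alternatives). Mitosis and DNA replication genes were raised less than in HCC1428, by median differences of -2.50 and -1.89 in MM134 and -2.11 and -1.56 in MM330, and these held with an estimated correlation (adjusted p = 0.00091 for both in MM134 and 0.0025 for both in MM330). Starting levels differed. The proliferation gene MKI67, chosen after its values were seen, stood at 973 ± 54 CPM in siNT of MM134, 329 ± 11 in MM330 and 116 ± 5 in HCC1428. In siNT_E2 it stood at 1020 ± 3.7, 536 ± 36 and 794 ± 34 CPM. Whether a higher starting level left less room for a rise was not tested. E2-induced targets were raised more in MM134 (median difference 0.48; adjusted p = 0.035 with an estimated correlation), as was Ribosome biogenesis (0.47; 0.0034). Cholesterol synthesis was lower in MM330 (-0.63; 0.001). The Fibroblast list, with 5 measured members, was lower in MM134 (-0.62; 0.038), by -0.40 without MM134 siNT replicate 2, by -0.99 with the lower pseudogene share, and not called without a filter on low counts (adjusted p = 0.14). In total 5680 genes differed between MM134 and HCC1428 and 6066 between MM330 and HCC1428, or 4516 and 4259 in the libraries with the lower pseudogene share.

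How far the E2 response depended on the receptor was addressed by siER_E2 against siNT_E2. In MM134, 10141 genes were called, 5198 higher and 4943 lower (9844 with the lower pseudogene share). ESR1 fell by 3.12 ± 0.04 on the log2 scale (adjusted p = 1.5e-22), MDC1 fell by 0.63 ± 0.05 and FOXA1 rose by 0.31 ± 0.03. TFF1 fell 7.57-fold, GREB1 8.88-fold, PDZK1 25.5-fold and MYC 5.46-fold. DEPP1, the gene most lowered by E2, rose most (5.68 ± 0.15), followed by the cholesterol exporter ABCA1 (3.54 ± 0.18), and CD34 fell most (-4.77 ± 0.25). All 49 E2-induced targets fell (median -1.56) and 11 of 12 E2-repressed targets rose (median 1.5), with PDCD4 falling. Ribosome biogenesis (median -0.64), Heat shock (-0.49), DNA replication (-0.44) and Cholesterol synthesis (-0.32) fell, and HSPA5 of the unfolded protein list fell 1.95-fold while DDIT4 of the same list rose 3.86-fold. That list had a median of -0.23, and its call was lost with an estimated correlation (adjusted p = 0.19).

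In MM330, 5788 genes were called after the receptor knockdown, 2692 higher and 3096 lower (4062 with the lower pseudogene share). ESR1 fell by 3.68 ± 0.08 and MDC1 by 0.98 ± 0.06. FOXA1 rose by 0.19 ± 0.06 (adjusted p = 0.03), a call lost without siER_E2 replicate 1 (0.16, adjusted p = 0.11), siNT_E2 replicate 2 (0.16, 0.1) or siNT_E2 replicate 3 (0.19, 0.058), and in the libraries with the lower pseudogene share (0.081). TFF1 fell 13.9-fold, GREB1 5.03-fold and MYC from 20.3 to 0.296 CPM. TMCO1, which encodes a calcium channel of the endoplasmic reticulum, rose most (2.06 ± 0.12), then RIPOR3 (1.85 ± 0.14) and the surface antigen PSCA (1.77 ± 0.07), and TCN1 fell most among genes with more than a handful of counts, from 27.7 to 0.24 CPM. TMCO1 rose 2-fold or more after all 3 knockdowns in all 3 lines, so its rise was not particular to ER knockdown. Of 48 E2-induced targets 44 fell (46 adjusted over the list alone; median -1.63) and CA12 rose, and 10 of 15 E2-repressed targets rose (11 adjusted over the list alone; median 0.64), with TXNIP falling. DNA replication (-0.37), DNA damage response (-0.32) and Mitosis (-0.24) fell with the preset correlation only (adjusted p = 0.6, 0.59 and 0.6 with an estimated correlation).

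In HCC1428, 9358 genes were called after the receptor knockdown, 4117 higher and 5241 lower (7492 with the lower pseudogene share). ESR1 fell by 1.00 ± 0.03, a smaller depth than in MM134 (difference -2.17) or MM330 (-2.71). MDC1 fell by 1.17 ± 0.06 and FOXA1 rose by 0.63 ± 0.04. GREB1 fell 4.38-fold, PDZK1 4.5-fold, TFF1 2.5-fold and PGR 2.16-fold. DEPP1 (4.55 ± 0.10), WNT11 (3.22 ± 0.11) and KCNJ13 (3.13 ± 0.13) rose most, and GJA1 (-2.87 ± 0.14), ADAMTS12 (-2.80 ± 0.12) and the cytokine gene IL20 (-2.61 ± 0.08) fell most. Of 49 E2-induced targets 46 fell (47 adjusted over the list alone; median -1.13), and 11 of 15 E2-repressed targets rose (median 1.13), with CYP24A1 falling. All 30 Mitosis and all 38 DNA replication genes fell (medians -1.63 for both), as did DNA damage response (-0.62, 26 of 33) and Cholesterol synthesis (-0.48, 20 of 23). Mitochondrially encoded genes rose by 0.30, and by 0.56 with the lower pseudogene share (adjusted p = 0.49 with an estimated correlation).

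Against HCC1428, the receptor knockdown lowered TFF1 further in MM134 (difference -1.65 ± 0.16, adjusted p = 6.1e-11) and MM330 (-2.51 ± 0.13, adjusted p = 2e-18), and GREB1 further in MM134 (-1.08). In MM330 GREB1 differed by -0.23 (adjusted p = 0.023). That call was lost without HCC1428 siER_E2 replicate 3 (adjusted p = 0.11), HCC1428 siNT_E2 replicate 2 (0.057) or MM330 siNT_E2 replicate 2 (0.06). FOXA1 rose less in both (-0.38 and -0.47), and MDC1 fell less in MM134 (0.49; MM330 0.16, adjusted p = 0.21). E2-induced targets fell further in MM134 and MM330 (median differences -0.51 and -0.63; adjusted p = 0.019 and 0.038 with an estimated correlation). Mitosis and DNA replication fell less, by 1.15 and 1.02 in MM134 and by 1.38 and 1.18 in MM330. These lists had also risen less with E2 in both lines. Genes called for a difference numbered 5256 and 5428 (3594 and 3595 with the lower pseudogene share). Because ESR1 fell less in HCC1428, these differences are not at equal depth of knockdown.

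Dependence on FOXA1 was addressed in the same way. In MM134, 9992 genes were called, 4943 higher and 5049 lower (9563 with the lower pseudogene share). FOXA1 fell by 1.97 ± 0.03 (adjusted p = 2.5e-22), ESR1 by 2.29 ± 0.04 and MDC1 by 0.35 ± 0.05. TFF1 fell 12.4-fold, PDZK1 11.2-fold, CXCL12 5.28-fold and GREB1 4.63-fold. HPCAL4 (4.85 ± 0.17), KIFC3 (4.54 ± 0.27) and LY6G6C (4.27 ± 0.13) rose most, and MS4A7 (-4.37 ± 0.09), the growth factor gene AREG (-4.33 ± 0.08) and HS3ST5 (-4.31 ± 0.17) fell most. Of 49 E2-induced targets 37 fell (median -1.29) and 4, among them HSPB8 and CA12, rose. E2-repressed targets rose (0.75, 8 of 12), while BCAS1 and IL1R1 fell. Epithelial adhesion rose (0.37, 17 of 24), with CTNNB1, the beta-catenin gene, up 2.73-fold and DSP down. The p53 targets had a median of 0.34 (adjusted p = 0.043; 0.095 with an estimated correlation; median 0.30 and adjusted p = 0.056 without siNT_E2 replicate 2). Among them CDKN1A rose 2.45-fold and MDM2 fell 1.61-fold. Mitosis, DNA replication and DNA damage response were also called by camera, and these 3 calls held with an estimated correlation. Ribosome biogenesis had a median of -0.32, and its call was lost with an estimated correlation (adjusted p = 0.1).

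In MM330, 8734 genes were called after the FOXA1 knockdown, 4344 higher and 4390 lower, and 7779 with the lower pseudogene share. Without siFOXA1_E2 replicate 1, which had the lowest total of all libraries, 9127 were called. FOXA1 fell by 1.86 ± 0.07, MDC1 by 0.71 ± 0.06 and ESR1 by 0.45 ± 0.07. TFF1 fell 4.41-fold, whereas GREB1 did not change (0.10 ± 0.05, adjusted p = 0.14; 0.16 and 0.005 without siFOXA1_E2 replicate 1). PDZK1 fell by 0.70 ± 0.17. TP63, a master factor of basal epithelium, rose from 0.564 to 15.3 CPM (4.75 ± 0.30), followed by KCNK12 (4.35 ± 0.22) and the retinoid carrier CRABP2 (4.28 ± 0.14). AREG fell 7.89-fold. Neither E2-induced targets (median -0.32, 24 lower and 15 higher of 48, adjusted p = 0.19) nor E2-repressed targets (adjusted p = 0.18) were called. All 38 DNA replication genes (median -1.94) and all 30 Mitosis genes (-1.02) fell, but neither list held with an estimated correlation (adjusted p = 0.2 and 0.22). In siFOXA1_E2 replicate 1 these lists lay above its siblings by medians of 0.78 and 0.56, and without it the falls were -2.33 and -1.26. Basal and mesenchymal genes rose (0.53; 0.2 with an estimated correlation), with SPARC up 16.1-fold against falls of FN1 and TWIST1. Epithelial adhesion rose by 0.34 (0.054 with an estimated correlation).

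In HCC1428, 9809 genes were called after the FOXA1 knockdown, 4412 higher and 5397 lower (9606 with the lower pseudogene share). FOXA1 fell by 1.64 ± 0.05, MDC1 by 0.90 ± 0.06 and ESR1 by 0.16 ± 0.03. TFF1 fell 3.12-fold, while GREB1, PDZK1 and PGR rose 1.57-fold, 1.54-fold and 1.34-fold. The calgranulin genes S100A9 (5.36 ± 0.17) and S100A8 (4.55 ± 0.08) rose most, followed by KCNJ13 (3.99 ± 0.12), and ITGAL (-2.27 ± 0.12), NDC80 (-2.25 ± 0.16) and SKA1 (-2.19 ± 0.09) fell most. E2-induced targets went both ways, 24 lower and 13 higher of 49 (median -0.18; adjusted p = 0.034, 0.35 with an estimated correlation and 0.058 with only the compared libraries). HSPB8 and BCL2 were among the 13. All 30 Mitosis genes and all 38 DNA replication genes fell, by -1.86 and -1.74. Mitochondrially encoded genes rose (0.49, all 13; adjusted p = 0.34 with an estimated correlation). The line differences for GREB1 were -2.90 in MM134 and -0.58 in MM330, for PDZK1 -4.15 and -1.33, for TFF1 -2.03 and -0.54, and for ESR1 -2.18 and -0.33. FOXA1 itself fell further in MM134 (-0.37, adjusted p = 2.6e-05) and in MM330 (-0.25, adjusted p = 0.0056; 0.062 with only the compared libraries), and MDC1 fell less in MM134 (0.50). E2-induced targets fell further in MM134 (median difference -0.96; adjusted p = 0.0044 with an estimated correlation) but not detectably in MM330 (-0.12; adjusted p = 0.38). Mitosis and DNA replication fell less in MM134 (1.3 and 1.14), where they had also risen less with E2 than in HCC1428. In MM330 the differences were 0.79 and -0.31, and both calls were lost with an estimated correlation (adjusted p = 0.17 and 0.4). That of DNA replication was -0.61 without siFOXA1_E2 replicate 1 and -0.15 without siFOXA1_E2 replicate 2 of MM330. Line differences were called for 6531 genes in MM134 and 4762 in MM330 (5591 and 4070 with the lower pseudogene share).

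The question of the series, whether MDC1 takes part in estrogen-driven expression in lobular carcinoma cells, was addressed by siMDC1_E2 against siNT_E2. In MM134, 8934 genes were called, 4505 higher and 4429 lower, 702 and 476 of them by 2-fold or more (9295 called with the lower pseudogene share). MDC1 fell by 2.13 ± 0.05 (adjusted p = 9.8e-19) and ESR1 by 2.16 ± 0.04 (adjusted p = 2e-20), whereas FOXA1 did not change (0.04 ± 0.03, adjusted p = 0.27). PDZK1 (ENSG00000174827.13, chromosome 1, 145670852 to 145708148), which encodes a membrane scaffold, fell 17-fold, GREB1 6.02-fold, CXCL12 3.39-fold, TFF1 1.95-fold and MYC 1.53-fold. FPR3 (4.99 ± 0.18), a receptor for formylated peptides, SIX2 (2.92 ± 0.08) and PLA2G16 (2.38 ± 0.04) rose most. CD34 fell most (-4.36 ± 0.24), and the repressor of E-cadherin SNAI1 fell from 12.3 to 1.03 CPM (-3.58 ± 0.21). Of 49 E2-induced targets 44 fell (median -0.96), while TSKU and CA12 rose, and 11 of 12 E2-repressed targets rose (median 1.02), with PDCD4 falling. The receptor tyrosine kinase gene RET fell 3.66-fold. Ribosome biogenesis fell (-0.36, 24 of 28 members), with NOLC1 down 2.03-fold, and Epithelial adhesion rose (0.28, 18 of 24), with JUP up 1.54-fold against a fall of DSP. DNA damage response fell (-0.19, 20 of 33), with the checkpoint kinase gene CHEK1 down 1.87-fold. Mitosis (-0.21) and DNA replication (-0.24) fell with the preset correlation only (adjusted p = 0.18 and 0.071 with an estimated correlation).

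In MM330, 3710 genes were called after the MDC1 knockdown, 1855 in each direction, 68 and 89 of them by 2-fold or more, and 2208 with the lower pseudogene share. MDC1 fell by 2.30 ± 0.06 and ESR1 by 0.96 ± 0.07 (adjusted p = 4.5e-08), and FOXA1 did not change (-0.09 ± 0.06, adjusted p = 0.4). PDZK1 fell 2.46-fold and GREB1 1.26-fold, whereas TFF1 and MYC were not called (-0.11 and 0.20, adjusted p = 0.6 and 0.31). With only the compared libraries, the same change of TFF1 was called (adjusted p = 0.025; 0.33 to 0.67 in the other alternatives). TMCO1 rose most (1.84 ± 0.12), as it also did by 2-fold or more after ER and FOXA1 knockdown in all 3 lines. IFI27 rose by 1.78 ± 0.52 (adjusted p = 0.022), a call lost without siMDC1_E2 replicate 2 (1.55, adjusted p = 0.086) or 3 (1.61, 0.069), or siNT_E2 replicate 1 (1.68, 0.074), 2 (1.82, 0.059) or 3 (1.85, 0.065). It was lost as well with limma-voom (1.68, 0.076) and with the lower pseudogene share (1.51, 0.13), and held in the other 6 alternatives. The histone gene HIST1H2BK fell most (-1.67 ± 0.06). Of 48 E2-induced targets 23 fell (26 adjusted over the list alone; median -0.26; adjusted p = 0.17 with an estimated correlation), while TSKU, IGFBP4, CA12 and RARA rose. E2-repressed targets rose by 0.33 (0.17), with CCNG2 falling. Small rises of DNA replication (0.24, 9 of 38), Mitosis (0.20, 9 of 30), Cholesterol synthesis (0.21, 11 of 23), Heat shock (0.13), Unfolded protein and amino acid stress (0.11) and Interferon response (0.36) were called with the preset correlation, and none held with an estimated correlation (adjusted p = 0.46, 0.46, 0.17, 0.17, 0.34 and 0.46). DNA damage response was not called (adjusted p = 0.86).

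In HCC1428, 5319 genes were called after the MDC1 knockdown, 2410 higher and 2909 lower, 131 and 126 by 2-fold or more (5329 called with the lower pseudogene share). MDC1 fell by 1.94 ± 0.06 (adjusted p = 2.9e-13). ESR1 fell by only 0.12 ± 0.03 (adjusted p = 0.01; -0.10 and 0.061 without siMDC1_E2 replicate 2, -0.10 and 0.051 with only the compared libraries), and FOXA1 rose by 0.23 ± 0.04. PDZK1 fell 1.77-fold, GREB1 1.48-fold and TFF1 1.33-fold. MYC rose by 0.15 (adjusted p = 0.025), a call lost with the replicate block (0.10, 0.2) and without siMDC1_E2 replicate 2 (0.12, 0.12), siNT_E2 replicate 2 (0.15, 0.063) or siNT_E2 replicate 4 (0.11, 0.12). The interleukin receptor gene IL1R1 (1.79 ± 0.06), EPHA4 (1.56 ± 0.08) and CLCA2 (1.48 ± 0.04) rose most, and ABHD12B (-1.40 ± 0.04) and the kinase gene FRK (-1.34 ± 0.08) fell most. Of 49 E2-induced targets 28 fell (31 adjusted over the list alone; median -0.26), with STC2 and CA12 rising, and 8 of 15 E2-repressed targets rose (0.31), with CYP24A1 falling. Mitosis (-0.66, 29 of 30 members), DNA replication (-0.48, 36 of 38) and DNA damage response (-0.26, 21 of 33) fell. Mitochondrially encoded genes rose by 0.30, a call lost with an estimated correlation (adjusted p = 0.27). H2AFX, the histone whose phosphorylated form MDC1 binds, fell 1.52-fold.

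Against HCC1428, MDC1 knockdown lowered ESR1 further in MM134 (difference -2.03 ± 0.07, adjusted p = 3.2e-23) and in MM330 (-0.84 ± 0.07, adjusted p = 6.9e-11). The knockdown of MDC1 itself did not differ detectably between MM134 and HCC1428 (-0.19 ± 0.09, adjusted p = 0.18) and was deeper in MM330 than in HCC1428 (-0.36 ± 0.09, adjusted p = 0.0052). FOXA1 differed by -0.32 in MM330. In MM134 it differed by -0.19 (adjusted p = 0.034), a call lost in several fits that left out a single library (adjusted p from 0.051 to 0.094). In MM134, PDZK1 (-3.26), GREB1 (-2.01) and TFF1 (-0.54) fell further than in HCC1428. MYC differed by -0.75, falling in MM134 only. Of 50 E2-induced targets 38 differed downward, against 1 the other way (median difference -0.72; adjusted p = 7.1e-05 with an estimated correlation). In MM330 the differences were -0.48 for PDZK1 (adjusted p = 0.0078; 0.053 with the lower pseudogene share), -0.85 for PGR (0.00062) and -1.57 for CXCL12 (0.0019), which fell from 1.18 to 0.531 CPM there and was called within the line only with limma-voom or the compared libraries alone (adjusted p = 0.012 and 0.016, against 0.092, and 0.073 to 0.35 in other alternatives). GREB1 fell less (0.24, adjusted p = 0.033; 0.073 with the lower pseudogene share). That call was lost without MM330 siMDC1_E2 replicate 2 (0.19, adjusted p = 0.14), MM330 siNT_E2 replicate 1 (0.21, 0.092) or 3 (0.24, 0.055), HCC1428 siMDC1_E2 replicate 2 (0.21, 0.11) or 3 (0.24, 0.066), or HCC1428 siNT_E2 replicate 3 (0.23, 0.078) or 4 (0.23, 0.076). TFF1 (0.30, adjusted p = 0.13) was called in 4 of 8 alternatives (adjusted p from 0.002 to 0.17). E2-induced targets in MM330 did not differ detectably from HCC1428 (-0.02; adjusted p = 0.6). Ribosome biogenesis fell further in MM134 (-0.29; 0.013 with an estimated correlation). Mitosis and DNA replication, which fell in HCC1428, differed upward in MM330 (0.79 and 0.74; 0.0023 for both), where their medians were not below 0. In MM134 they fell less, with the preset correlation only (0.42 and 0.25; 0.12 and 0.25). Both lists had risen less with E2 in MM134 and MM330 than in HCC1428. Cholesterol synthesis differed by 0.28 in MM330 (0.014). Differences were called for 3993 genes in MM134 and 2950 in MM330 (3667 and 2007 with the lower pseudogene share).

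**Figure D3:**
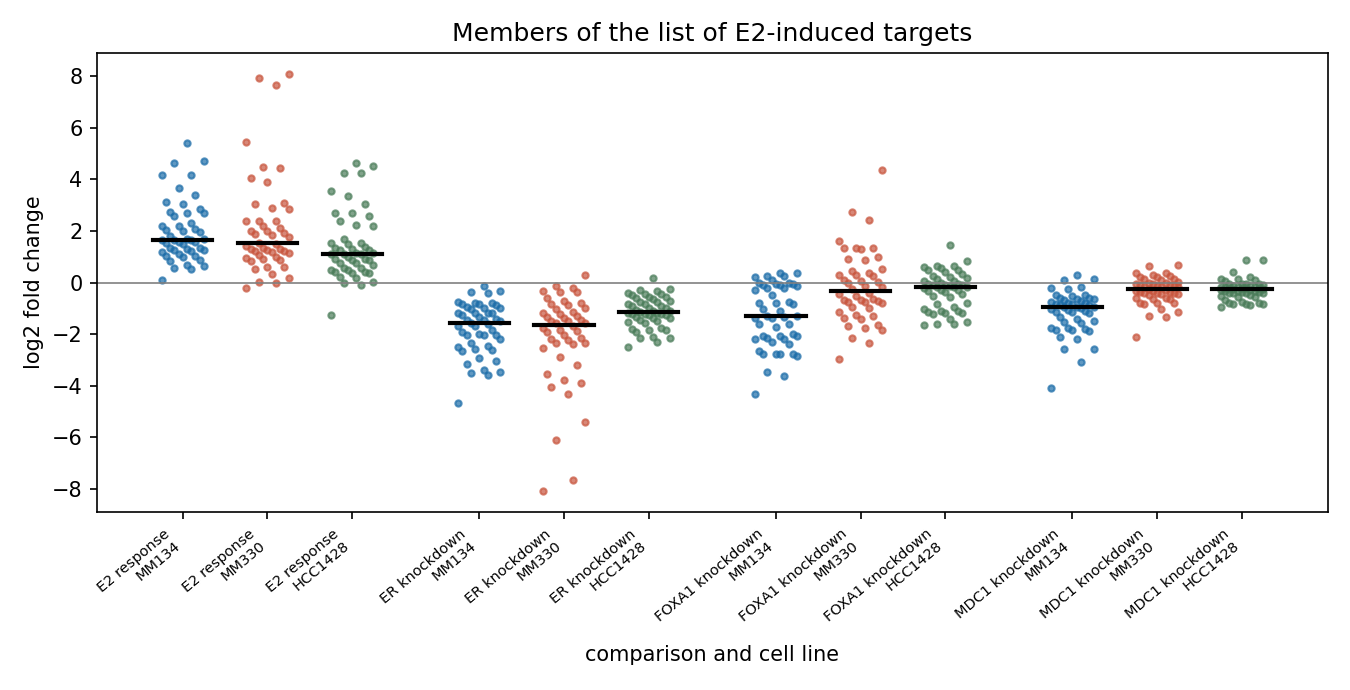
Log2 fold change (vertical axis) of each measured member of the list of E2-induced targets, 48 or 49 genes per line, in the 4 comparisons within each line, with 1 point per gene and a bar at the median. After MDC1 knockdown the medians were -0.96 in MM134 and -0.26 in both MM330 and HCC1428.

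Across all genes called in both comparisons, knockdowns were set against the E2 response. Among genes raised by E2, ER knockdown lowered 79.3% in MM134, 67.3% in MM330 and 82.7% in HCC1428. FOXA1 knockdown lowered 57%, 60.7% and 64.3%, and MDC1 knockdown 58.5%, 22.1% and 41.8%. Among all genes tested, MDC1 knockdown lowered 25%, 10.4% and 15.9%. MDC1 knockdown reversed 5544 genes in MM134, 1114 in MM330 and 3973 in HCC1428, where independent calls would give 2429, 488 and 1467. It moved 1001, 603 and 398 genes in the same direction as E2, ER knockdown 338, 155 and 103, and FOXA1 knockdown 1583, 869 and 1238. ER knockdown reversed 7471, 3090 and 7839 genes (2757, 763 and 2585 with independent calls), and FOXA1 knockdown 5293, 2648 and 5881 (2716, 1149 and 2707). With the lower pseudogene share, MDC1 knockdown reversed 5767, 592 and 3811 genes, ER knockdown 7462, 1959 and 6096, and FOXA1 knockdown 5186, 1800 and 5265. In 20 fits per line of counts simulated with equal group means, edgeR called at most 1 gene as reversed by ER or FOXA1 knockdown in any line, at most 1 by MDC1 knockdown in MM134 and 0 in MM330 and HCC1428. Genes varied independently in these counts, without deviations that run through a whole library such as those of the pseudogene share. The simulated numbers may therefore understate chance calls. In HCC1428, splits that follow the pseudogene share called 360 genes for E2 and 412 for ER knockdown. The E2 comparison and the knockdowns share the siNT_E2 libraries, which by itself gives opposite signs. The correlation across genes of E2 response and MDC1 effect was -0.66 in MM134, -0.33 in MM330 and -0.47 in HCC1428, against medians of -0.51, -0.52 and -0.53 in sets simulated with no effect. The covariances were -0.231, -0.06 and -0.135. Simulated covariances reached -0.094, -0.193 and -0.132, so that of MM330 lay within the simulated range. The simulated sets drew deviations from all libraries of a line, in MM330 also from siFOXA1_E2 replicate 1, which stood apart from its siblings. That library is in neither of these comparisons and may widen the MM330 range, so the range does not decide whether sharing alone explains the MM330 value. For ER knockdown the correlations were -0.83, -0.76 and -0.90 (simulated medians -0.5, -0.53 and -0.52), and the covariances of -0.335, -0.208 and -0.406 lay beyond the simulated -0.087, -0.191 and -0.126. For FOXA1 knockdown the correlations were -0.43, -0.26 and -0.46 (-0.54, -0.57 and -0.52). Its covariances were -0.187, -0.105 and -0.225 against -0.085, -0.206 and -0.141, so that of MM330 again lay within the simulated range. All of these correlations lay within the ranges of their simulated sets, which for ER knockdown reached -0.93, -0.89 and -0.92. The correlations alone therefore do not set the knockdowns apart from sharing of the siNT_E2 libraries. Genes are not independent replicates, and these correlations are over genes.

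**Figure D4:**
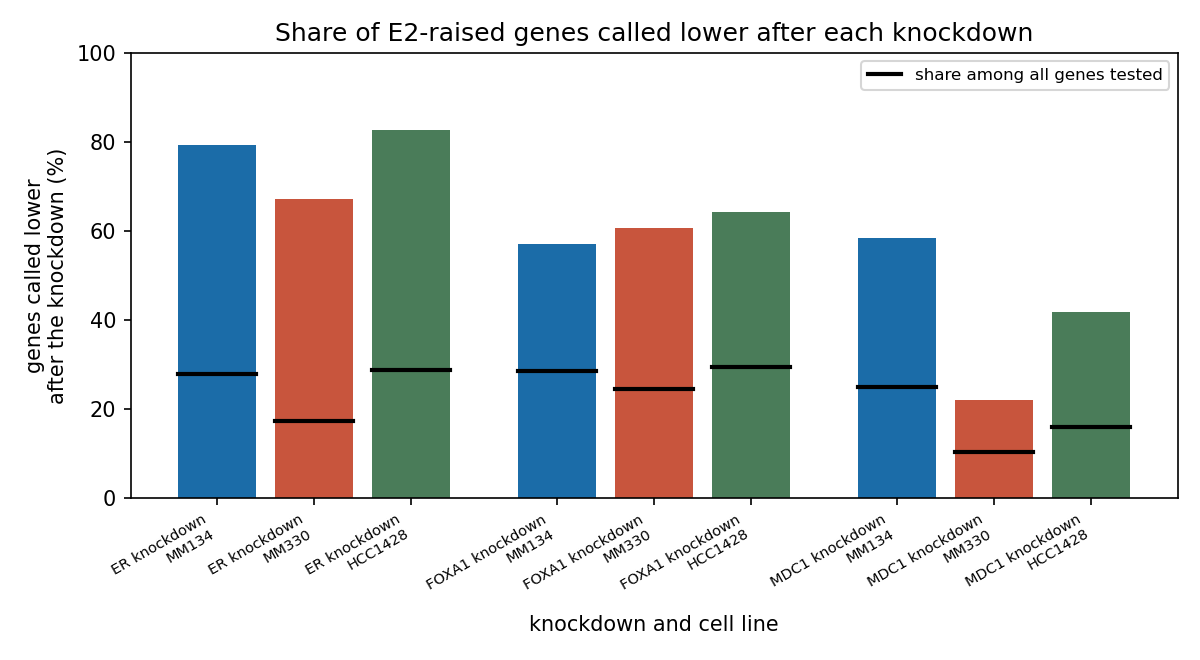
Percent of genes raised by E2 that were called lower after each knockdown (bars), by cell line, with a black line at the percent of all genes tested that were called lower. For MDC1 knockdown the bars stand at 58.5%, 22.1% and 41.8% and the lines at 25%, 10.4% and 15.9% in MM134, MM330 and HCC1428.

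Knockdown effects overlapped with each other. MDC1 and ER knockdown moved 6185 genes the same way in MM134, 1942 in MM330 and 4090 in HCC1428 (2554, 602 and 1376 with independent calls; 6191, 1155 and 3770 with the lower pseudogene share). Their correlation across genes was 0.71, 0.47 and 0.50, against simulated medians of 0.51, 0.56 and 0.56. All lay within the simulated ranges (highest 0.88, 0.95 and 0.93). The covariance was 0.248 in MM134, beyond the simulated highest of 0.089, and 0.088 and 0.119 in MM330 and HCC1428, within the simulated ranges (highest 0.166 and 0.143). The MM330 range again included deviations of siFOXA1_E2 replicate 1, which is in neither of these knockdown groups and may widen it. MDC1 and FOXA1 knockdown shared 5654, 1792 and 3529 genes (2515, 908 and 1440 with independent calls; 5592, 1134 and 3519 with the lower pseudogene share), with covariances of 0.204, 0.065 and 0.13 against simulated highest values of 0.082, 0.223 and 0.126. ER and FOXA1 knockdown shared 6180, 3215 and 5795 genes (2855, 1418 and 2540; 5728, 2261 and 4865), with covariances of 0.244, 0.124 and 0.189 against 0.087, 0.156 and 0.168.

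Over the 12 comparisons within lines, 101 of 192 list results were called with the preset correlation, and 51 of these held with an estimated correlation. Those that held were E2-induced and E2-repressed targets for E2 and ER knockdown in every line, for MDC1 knockdown in MM134 and HCC1428 and for FOXA1 knockdown in MM134. Mitosis and DNA replication held in all comparisons of HCC1428, DNA replication for E2 and for ER and FOXA1 knockdown of MM134, and Mitosis for FOXA1 knockdown of MM134. DNA damage response held in all comparisons of MM134 and in HCC1428 except for FOXA1 knockdown. Cholesterol synthesis and Heat shock held for E2 and ER knockdown of MM134 and HCC1428. Ribosome biogenesis held for E2, ER and MDC1 knockdown of MM134 and ER knockdown of HCC1428, and Epithelial adhesion for FOXA1 and MDC1 knockdown of MM134. Fibroblast, Immune cell and Endothelial had fewer than 5 measured members within lines and were not tested there. Median, mean and test differed in sign in 23 of 192 list results, and 0 of the 23 passed the threshold in camera. Examples were Basal and mesenchymal after MDC1 knockdown in MM134 (median 0.36, mean -0.11) and p53 targets with E2 in HCC1428 (median -0.02, mean 0.25).

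**Figure D5:**
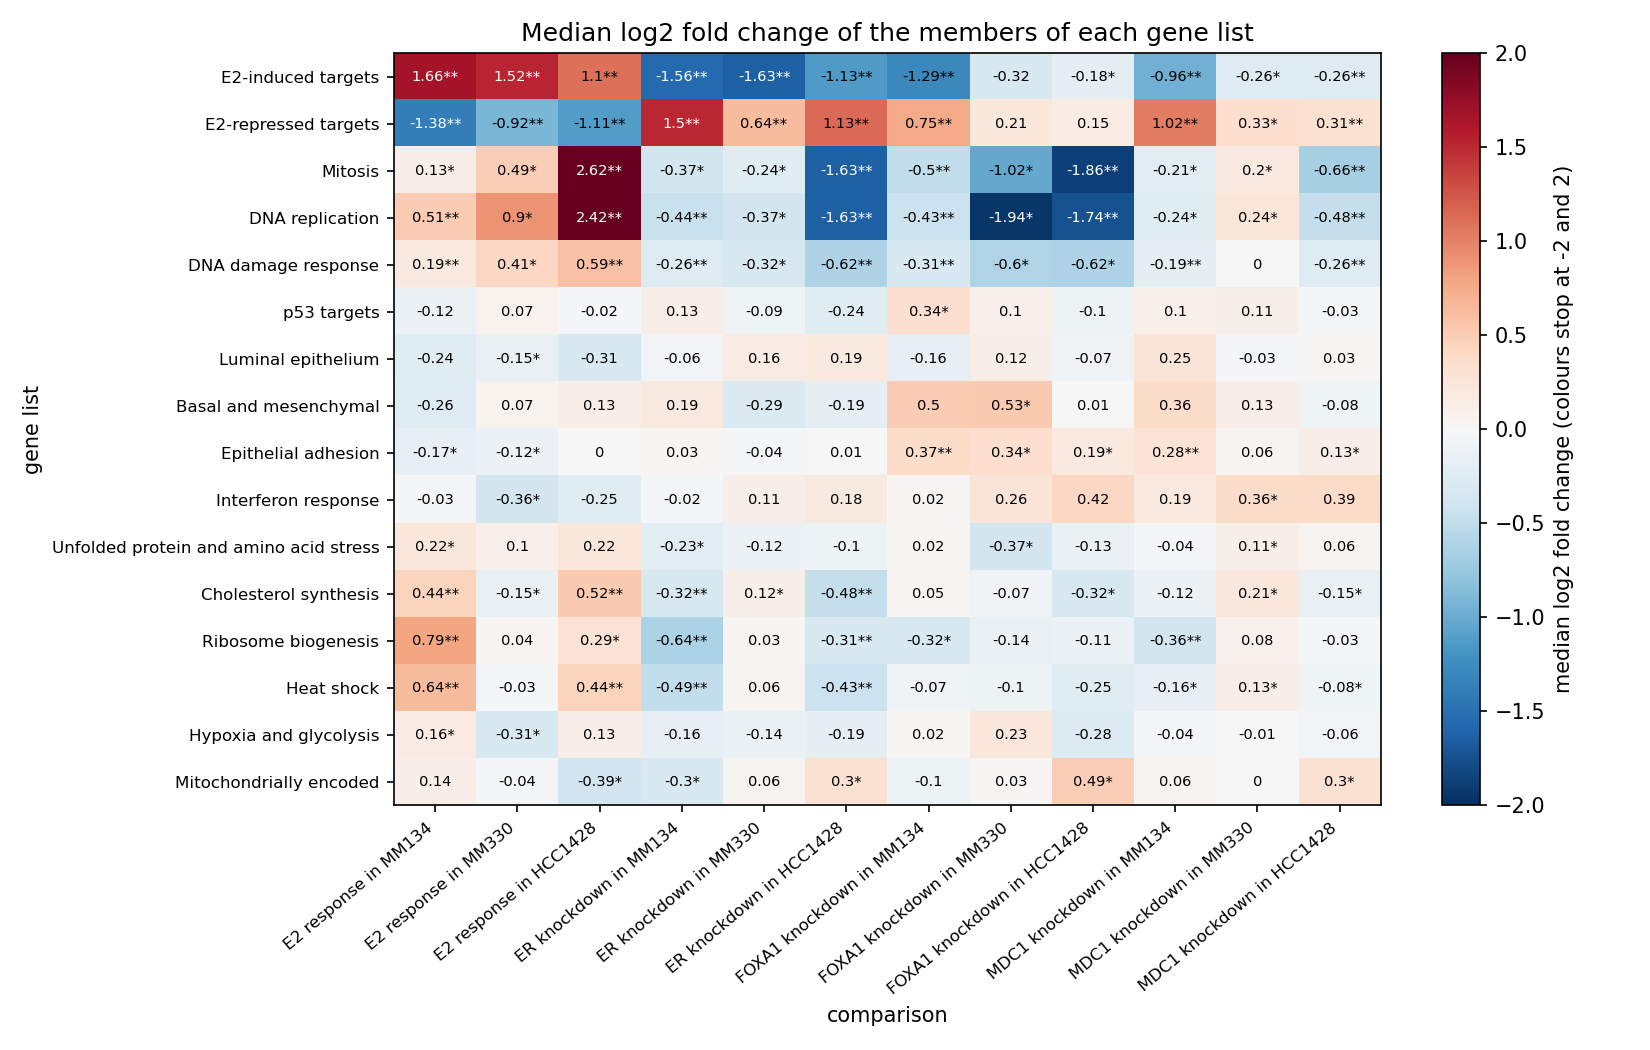
Median log2 fold change (colour and printed value) of the members of 16 gene lists in the 12 comparisons within lines; a single asterisk marks lists called by camera with the preset correlation and a double asterisk those also called with an estimated correlation. Mitosis had a median of 2.62 with E2 in HCC1428, 0.49 in MM330 and 0.13 in MM134.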

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

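The tests of shared reads, of genomic DNA and of library size for the pseudogene share, of a wrong knockdown label for the library that stands apart, and of the depth of the MDC1 knockdown were chosen only after the result was seen, as were the class of libraries by pseudogene share and every value from its lower class. The results below differed between a lobular line and HCC1428 by a test of the difference itself. For E2 these were 5680 genes in MM134 (2608 higher, 3072 lower) and 6066 in MM330, for ER knockdown 5256 and 5428, for FOXA1 knockdown 6531 and 4762, and for MDC1 knockdown 3993 and 2950. Cell line is a difference of the design, with 1 ductal line and 2 lobular ones, so it cannot be separated from carcinoma type and stays open, untested.

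For E2, the differences in log2 fold change from HCC1428 in MM134 were 1.19 for ESR1, 0.60 for FOXA1, -1.36 for MDC1, 1.11 for GREB1 and 2.69 for MYC, and list medians differed by 0.48 for E2-induced targets, -2.50 for Mitosis, -1.89 for DNA replication, 0.47 for Ribosome biogenesis and -0.62 for Fibroblast (-0.40 without MM134 siNT replicate 2). In MM330 they were 0.35 for ESR1, 0.31 for FOXA1, -0.90 for MDC1, -0.39 for GREB1 and 5.44 for MYC, with -2.11 for Mitosis, -1.56 for DNA replication and -0.63 for Cholesterol synthesis. Starting levels differed, with the proliferation gene MKI67 in siNT at 973 CPM in MM134, 329 in MM330 and 116 in HCC1428. After ER knockdown the differences in MM134 were -2.17 for ESR1, -0.38 for FOXA1, 0.49 for MDC1, -1.65 for TFF1 and -1.08 for GREB1, with -0.51 for E2-induced targets, 1.15 for Mitosis and 1.02 for DNA replication. In MM330 they were -2.71 for ESR1, -0.47 for FOXA1 and -2.51 for TFF1, with -0.63, 1.38 and 1.18 for the same lists. After FOXA1 knockdown they were, in MM134, -2.18 for ESR1, -0.37 for FOXA1, 0.50 for MDC1, -2.03 for TFF1, -2.90 for GREB1 and -4.15 for PDZK1, with -0.96, 1.3 and 1.14 for the lists. In MM330 they were -0.33 for ESR1, -0.25 for FOXA1, -0.54 for TFF1, -0.58 for GREB1 and -1.33 for PDZK1, with 0.79 for Mitosis and -0.31 for DNA replication (-0.61 without MM330 siFOXA1_E2 replicate 1 and -0.15 without replicate 2), calls that were lost with an estimated correlation (adjusted p = 0.17 and 0.4). After MDC1 knockdown they were, in MM134, -2.03 for ESR1, -0.54 for TFF1, -2.01 for GREB1, -3.26 for PDZK1 and -0.75 for MYC, with -0.72 for E2-induced targets, -0.29 for Ribosome biogenesis, 0.42 for Mitosis and 0.25 for DNA replication, the last pair lost with an estimated correlation (adjusted p = 0.12 and 0.25). In MM330 they were -0.84 for ESR1, -0.32 for FOXA1, -0.36 for MDC1, -0.48 for PDZK1, -0.85 for PGR, -1.57 for CXCL12 and 0.24 for GREB1 (0.19 and adjusted p = 0.14 without MM330 siMDC1_E2 replicate 2), with 0.79 for Mitosis, 0.74 for DNA replication and 0.28 for Cholesterol synthesis.

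Other splits of the same libraries were counted for each number of called genes. Within lines, 3 libraries against 3 make 10 splits, too few for a share under 0.05, and 1 split, the real one, gave each count. The highest other split called 0 genes by edgeR for all 4 comparisons of MM134 and of MM330 and for FOXA1 and MDC1 knockdown in HCC1428, against real counts of 3710 to 10141; counts of other splits at an unadjusted p, or by other tools, were not made. For HCC1428 the highest other split called 360 genes for E2 (real 10028) and 412 for ER knockdown (real 9358), and in both it was the split that follows the pseudogene share; with the lower share alone, 8869 and 7492 genes were called. For line differences, 100 splits within lines were made in fits of the 12 compared libraries. A split that mixes the groups of a line also removes its treatment effect and moves it into the spread between libraries. The splits thus cannot exclude chance for a difference between lines. The same holds for the splits within a line. Each of the others mixed treated and control libraries, and the added spread by itself lowers the number of genes called. Their low counts are therefore no evidence against chance for the counts within lines. Only the real split gave a count as large for E2 in MM134 (real 5823, highest other 4054) and ER knockdown in MM134 (5511, 3556) and MM330 (5134, 3903). The same held for FOXA1 knockdown in MM134 (7553, 3855) and MM330 (3755, 3131) and MDC1 knockdown in MM330 (2948, 1250). For E2 in MM330, 2 of 100 splits gave a count as large (real 5745, highest other 8590), the other of which kept the real groups of a line. For MDC1 knockdown in MM134, 5 of 100 gave a count as large (real 4999, highest other 5242). All 4 others kept the real groups of a line, and with them the effect in that line, so they say little about chance; the highest split that mixed both lines called 0 genes by edgeR.

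In 11 of 45 libraries the share of counts at processed pseudogenes was higher (0.337% to 0.494%, against 0.123% to 0.158%). The total of all 11 lay inside the range of the other libraries, which argues against library size. Antisense, lincRNA and intronic genes held at most a log2 ratio of 0.05 more of the counts, which argues against genomic DNA or unspliced RNA. Over 158 parent genes, the median difference was 1.90 for processed pseudogenes, -0.05 for parents and -0.01 for the sum of both. Most parents held far more counts than their pseudogenes, so the sum could hardly move whatever the cause. Where pseudogenes held more counts than the parent, the sum rose, by 1.25 for RPS10, 1.16 for EIF4A1, 0.84 for NDUFV2 and 0.18 for ENPP7. These parents stood at only 1.54, 2.68, 1.08 and 0.0554 CPM. Elsewhere the sum was lower, by -0.64 for RPL41, -0.28 for RPL21 and -0.21 for RPS26. RPL41 itself stood at 301 CPM and differed by -0.65, a loss that did not reappear at its own pseudogenes. A different assignment, in the 11 libraries, of reads shared by a parent and its pseudogenes stays a candidate that the sum does not decide. What made the libraries differ is not given by the labels, and no biological explanation was tested.

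MM330 siFOXA1_E2 replicate 1 had counts at 18829 genes, whereas its siblings, thinned to its total of 21.0 M, kept 23632 and 23629. The lower of these exceeds it by 4800, which argues against library size alone. Marker genes of MM134 and of HCC1428 stood at a median of 0% of those lines, against 0.14% and 0.051% in its siblings. That argues against a large share of RNA of another line. Because the library had counts at fewer genes, a small share could have been missed. Its FOXA1 level was 0.35 of the lowest in the other groups of MM330, which argues against a wrong knockdown label from those groups. Against its siblings, list medians lay at 0.78 for DNA replication, 0.61 for Interferon response, 0.56 for Mitosis, 0.32 for DNA damage response, 0.26 for Hypoxia and glycolysis and -0.30 for Mitochondrially encoded genes (the siblings differed by -0.22 and 0.22 in the first pair), so fewer starting molecules and another state of the cells stay open, untested.

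E2-induced targets fell further after MDC1 knockdown in MM134 (median -0.96) than in HCC1428 (-0.26), alongside ESR1 (-2.16 against -0.12). MDC1 itself changed by -2.13 in MM134 and -1.94 in HCC1428, a difference of -0.19 (adjusted p = 0.18 in the edgeR fit of all 45 libraries). In MM330 it fell by a further -0.17 (-2.30 against -2.13, a difference not tested) while the targets fell by only 0.26. That argues against a deeper MDC1 knockdown only if lines respond alike to loss of MDC1, which was not tested. The pseudogene share is argued against by a median difference of -0.76 in the libraries with the lower share. A loss of ESR1 carrying the fall of its targets in MM134 stays open, untested. Within MM134 the targets fell most after ER knockdown, then FOXA1, then MDC1 knockdown, the order of ESR1 loss (65.9, 117 and 129 CPM). In MM330 and HCC1428, FOXA1 and MDC1 knockdown did not follow that order. In MM330 ESR1 fell by 0.96 and the targets by the same 0.26 as in HCC1428. ER knockdown in HCC1428 lowered ESR1 by 1.00 and the targets by 1.13. These values go against a common relation of ESR1 transcript loss to target loss across lines, but say little about MM134 alone. Receptor protein was not measured. An effect of MDC1 on the targets apart from ESR1 and an effect of the siRNA itself stay open as well, since 1 siRNA label per target was used.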

How the results depend on the processing

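The pseudogene class term and the fit of libraries with the lower pseudogene share alone were chosen only after the result was seen. With the lower share alone, which leaves fewer samples (1 each in HCC1428 siNT and siER_E2, assumed to vary like the other groups), counts moved by over 1.5 times for E2 in MM330 (3092), MDC1 knockdown in MM330 (2208), the line difference in ER knockdown in MM330 (3595), reversal in MM330 by ER (1959) and MDC1 knockdown (592), and overlap in MM330 of MDC1 with ER (1155) and FOXA1 knockdown (1134). The list Mitochondrially encoded was called upward there after MDC1 knockdown in MM330 (0.15), where the main fit had not called it (median 0, adjusted p = 0.96 by camera). With fry, lists took the direction opposite to camera for Luminal epithelium with E2 in MM134 (-0.24) and FOXA1 knockdown in HCC1428 (-0.07). The same held for Basal and mesenchymal after FOXA1 knockdown in MM134 (0.5) and Unfolded protein and amino acid stress after ER knockdown in HCC1428 (-0.1). Camera with the preset correlation had called none of these, so no called list was reversed. The values are medians, the direction is that of fry, and the cause was not tested. All other counts stayed within 1.5 times under RLE scaling, no low-count filter, the replicate block, DESeq2, limma-voom, the pseudogene class term and the compared libraries only, for example 4238 to 5569 for MDC1 knockdown in HCC1428, and leaving out single libraries gave 2672 to 3261 in MM330 against 3710. Of 101 list calls within lines, 50 were lost with an estimated correlation, and 49 of 83 between lines.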

Other observations

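No test in this part was chosen only after the result was seen, but the genes named below were chosen after their values were seen. Genes that changed 2-fold or more in the same direction in all 3 lines were counted among 14933 genes tested in each. E2 raised 80 and lowered 46 such genes, against 0.49 and 0.28 with independent lists. Among those raised were SLC7A5, an amino acid transporter (log2 3.19 in MM134, 1.56 in MM330 and 1.87 in HCC1428), IGFBP4, which binds insulin-like growth factors (2.75, 3.05 and 2.23), the kinase receptor gene RET (2.32, 2.86 and 2.69), the lysosomal protease gene CTSD (1.34, 1.21 and 1.39) and ELOVL2, which lengthens fatty acids (2.20, 2.37 and 2.20). ER knockdown raised 37 and lowered 82, and FOXA1 knockdown raised 125 and lowered 87.

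MDC1 knockdown changed 9 genes in this way, MDC1 included, where independent lists would give 0.01, so a set of genes that responds alike in all 3 lines is consistent with the count of 9. FYCO1, RHOQ, TMCO1 and ZNF658B rose, and FRK, HIST1H2BK, MDC1, MGAM and TMED10 fell. TMED10, which carries cargo between endoplasmic reticulum and Golgi, fell after MDC1 knockdown (-1.96 in MM134, -1.18 in MM330 and -1.26 in HCC1428) but not 2-fold after ER knockdown (-0.02, 0.12 and 0.01) or FOXA1 knockdown (0.02, 0.27 and -0.03). TMCO1 rose after all knockdowns, by 2.15, 1.84 and 1.23 with siMDC1, 2.10, 2.06 and 1.40 with siER and 2.02, 1.97 and 1.11 with siFOXA1. The 3 knockdowns of a line share its siNT_E2 libraries, none of the 45 libraries was labelled as untransfected, and effects of the siRNAs themselves were not tested.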
